A study of Mus musculus with 2 samples.

How the data were processed

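Spinal cord microglia were sorted from control mice and from mice of an atopic diathesis model, and 1 sample of each was measured. Per the labels' protocols, total RNA was isolated with TRIzol and a column kit, and cRNA was amplified and labelled with Cy3 by a kit for low amounts of RNA. Both arrays are 1-colour Agilent mouse arrays on 1 slide, so slide and group are not mixed up, but position on the slide and group cannot be separated. The submitters' titles call the atopic diathesis sample activated and the control sample normal. How the model was made and how many animals a sample holds is not given in the sources used here.

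The deposited scanner files hold 1 row per spot as fluorescence intensity on a linear scale, made with Agilent Feature Extraction. Per the file headers its version was 10.7.1.1, whereas the submitters' processing notes name 9.5.1.1. The processed signal in these files is background-subtracted by that software. The deposited series table holds 1 intensity per probe and array on a linear scale, with a median of 6.64 in each column. Its ranks within each array matched the scanner values (Spearman correlation of 1 across probes), and the sorted values of both columns were equal within 0.01 on the log2 scale for 100% of ranks, which is what quantile normalization between the arrays gives. No source used here states that step, and direction and centring raise no doubt because the values are not ratios. No spike-in values were used.

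Each array holds 59305 spots of 55681 probes apart from 3671 control spots, which were left out. Probe coordinates are those of the files, on build mm9. Gene names came from matching each probe's accession, without versions, to RefSeq genes of GRCm38.p6, used for names only, and 27235 of 55681 probes matched. The other probes kept the name in the file, which can be old. In all 35019 gene names resulted.

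The log2 processed signal minus the 75th percentile of all probes of that array was the main scale. Spots marked as outliers (136 and 122) were left out, and spots of one probe were averaged. A gene counted as measured where at least 1 probe was well above background on both arrays, and its value is the mean over such probes. Because under 28% of probes were detected on either array, the 75th percentile of signal, 20.7 in control and 28.6 in atopic diathesis, fell among dim probes, and the median of the 9217 measured genes came to -0.50. Among the probes detected on both arrays the 75th percentiles were 785 and 725. For that reason single genes and lists are given relative to the median measured gene, a choice made after the data were seen, and counts are given on both scales. A gene above background on 1 array only has a bound in place of a fold: its signal on the bright array over the higher of the dim array's lowest signal well above background and the dim probe's own signal, at its brightest probe.

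With 1 array per group there is no residual error, so no test was made and no p-value is given. The number of arrays limits the precision. Of the 399 probes printed 10 times per array, the 101 well above background on both arrays with at least 5 usable spots gave an SD between spots of 0.15 (control) and 0.14 (atopic diathesis) on the log2 scale. The intervals from these cover spot error only. Probes of one gene often differed: among 1467 genes with at least 2 measured probes, all probes lay on the same side of the median gene in 62.6%.

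Before the data were examined, 42 gene lists were fixed, which hold 672 genes of the array, 41 of them in more than 1 list. Of these lists 29 had at least 4 measured genes. For each of these the median was ranked among 10000 random lists of the same size, drawn from 20 bins of mean signal, and a list was said to stand apart below percentile 2.5 or in the highest 2.5%. This describes the pair of arrays and is not a test between groups. The genes named were fixed by rule: the 15 highest and 15 lowest genes with a symbol, with a brighter signal at or above the median of measured genes on that array and all measured probes of the same sign; from each list the 4 measured genes with the largest difference, or all where a list has at most 8 genes; and the 5 highest bounds per direction. Further list members are named where 5 or fewer lay past 2-fold, or as well-known markers, and were chosen after their values were seen. Some list genes, of which the rule selects several, are not reported here, for reasons unrelated to their values, so the genes named are not all that the rule selects; they stay in the list counts and percentiles. "Higher" and "lower" without a size mean at least 2-fold from the median measured gene.

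Alternatives fixed before the data were examined were other scalings (median, 75th percentile of detected probes, quantile, loess with a span of 0.4), normexp background correction with an offset of 50, uncorrected signals, the deposited series table, other background filters, the brightest probe per gene, kept outlier spots, thresholds of 1.5-fold and 4-fold, list means, and list members that no other list names. Added afterwards were the median gene as reference, the brightest quintile of genes, random genes from the 50 nearest in signal, and leaving out probes that share 16 bases, on either strand, with probes of 10 or more gene names. On simulated data made from the control array with the spot error above, all 9217 genes being compared, 100% of genes with a log2 change of 1.5 and 100% of those with a change of 3 were found past 2-fold, and 0 of 9017 unaltered genes were. As only spot error was put in, this checks the script and says nothing about false differences from separate sorts or amplifications. Of 40 simulated lists without a shift 1 stood apart. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.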

Results

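Microglia, the resident macrophages of the central nervous system, were sorted from the spinal cord of control mice and of mice of an atopic diathesis model, and their total RNA was measured on 1-colour expression arrays. Atopic diathesis is a tendency to develop allergic disease. The comparison asks how gene expression in spinal cord microglia differs between these mice. It rests on 1 control array and 1 atopic diathesis array, and the labels do not say how many mice each sample holds. Of 55681 probes, 13430 (24.1%) were well above background on the control array and 15386 (27.6%) on the atopic diathesis array, and no spot was saturated. Genes with a probe well above background on both arrays numbered 9217. With 1 array per group no difference has a replicate check and no test can be made, so all values below describe these 2 samples. The only error available is that between repeated spots of one probe on an array. Pooled over 101 probes, it gave an SD of 0.20 for a log2 difference and a 95% interval of ±0.40. This is an average width, not fitted to the signal or number of probes of each gene. That interval leaves out the spread between animals, sorts and RNA amplifications. All log2 differences and folds are atopic diathesis over control, relative to the median measured gene, unless the scale is named.

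The largest differences went in both directions and belonged to genes of varied functions. Ccdc107 read 83.4-fold higher and Ankrd16 80.5-fold higher in atopic diathesis microglia, followed by Clpb, a mitochondrial protein disaggregase, at 59.3-fold. Their control signals were 24.1, 24.9 and 32.7, where the lowest signal well above background on that array was 19.8. These folds therefore rest on values near background. Each of these genes also has a second probe on the array that did not count as measured. Stip1, a co-chaperone that links Hsp70 and Hsp90, had signals of 126 in control and 6627 in atopic diathesis microglia, 54.0-fold higher. Zpr1, a zinc finger protein, was 69.4-fold lower, with log2 differences of -6.31 and -5.92 on its probes, which share sequence and are no separate readings. Vps45, a vesicle trafficking protein, was 46.2-fold lower and Fech, the ferrochelatase that inserts iron into protoporphyrin to form haem, 38.5-fold lower. Their signals in atopic diathesis microglia were 31.0 and 28.0, where the lowest signal well above background was 19.9.

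Further genes among the 15 highest were Myo1e, a class I myosin (52.5-fold), Zeb1, a transcriptional repressor (42.3-fold), the palmitoyltransferase gene Zdhhc6, Ank2, Bpnt2, Hace1, Tmem184b, Nek5, Jdp2, Stmn1 and Vapb, the last at 35.6-fold. The other 12 of the 15 lowest were Ciz1 (37.2-fold), Lemd2 of the inner nuclear membrane (37.0-fold), Anapc13, Pithd1, Sart3, Bnip1, Plxna4, Chml, Cyria, the mitochondrial aspartate aminotransferase Got2, Rad23b and Nacc2 (22.3-fold). On the dimmer array many of these 30 genes had a signal near background, and several have further probes that did not count as measured. Apart from Zpr1, each rested on 1 measured probe. Cyria was 22.7-fold lower on that probe, but its log2 difference was 0.57 once probes above background on a single array entered. In mm9 coordinates, the Ccdc107 probe lies on chromosome 4 at 43508719 to 43508778 (plus strand), the Ankrd16 probe on chromosome 2 at 11711824 to 11711883 (plus strand) and the brighter Zpr1 probe on chromosome 9 at 46089549 to 46089608 (plus strand).

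**Figure D1:**
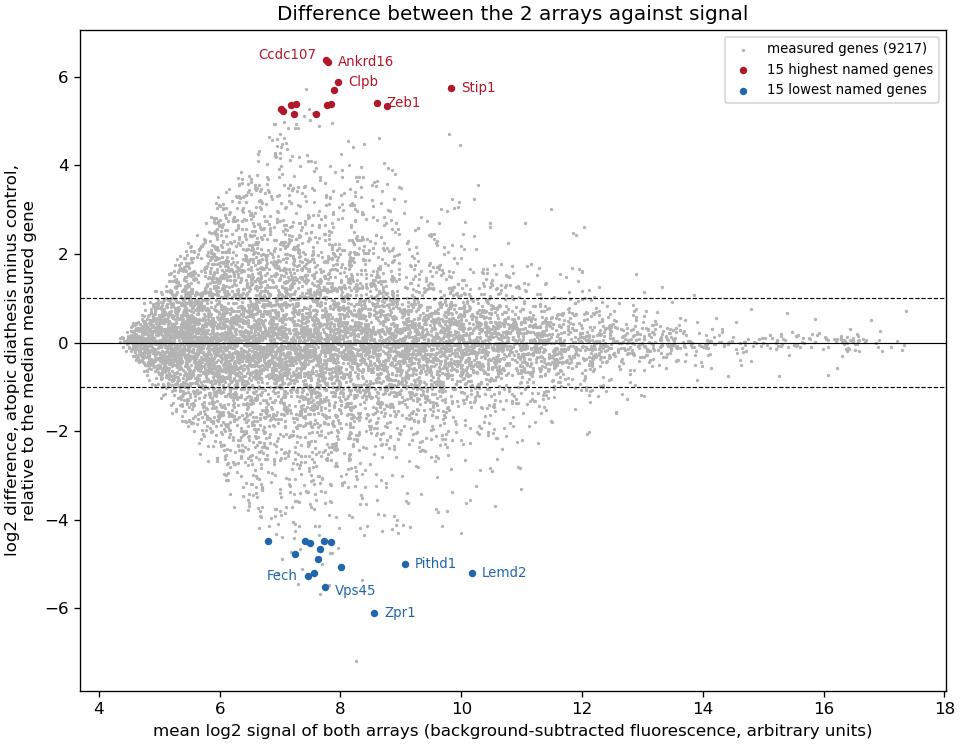
Log2 difference between the arrays, atopic diathesis minus control and relative to the median measured gene (vertical axis), against the mean log2 signal of both arrays in arbitrary fluorescence units (horizontal axis), with 1 point per measured gene. Red and blue points are the 15 highest and 15 lowest named genes and dashed lines mark 2-fold; 1596 genes lie on or above the upper line and 1436 on or below the lower.

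In all, 1596 genes were at least 2-fold higher and 1436 at least 2-fold lower than the median gene, 32.9% of those measured. At least 8-fold differences numbered 218 higher and 174 lower. Scaled by the 75th percentile of all probes, the choice made before the data were examined, the same threshold gave 988 higher and 2506 lower (28.3% higher). On that scale the median measured gene itself lay at -0.50, since the percentile fell among probes near background. Scaled by probes well above background on both arrays, the split was 1712 to 1307 (56.7% higher), and quantile normalization gave 1325 to 1831 (42% higher). The authors' own normalized values gave 1320 to 1821 (42% higher), normexp background correction 817 to 1177 (41.0%) and uncorrected signals 728 to 1120 (39.4%). With probes above background on at least 1 array the split was 3367 to 3846 (46.7% higher), and with no filter 3659 to 5065 (41.9%). Which direction prevailed therefore depended on the scaling. Dim and bright genes differed in how often they lay past 2-fold: 46.6% did so in the middle quintile of mean signal and 15.2% in the brightest. Across genes, which are not independent replicates, the normalized log2 signals of both arrays correlated with r = 0.85.

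**Figure D2:**
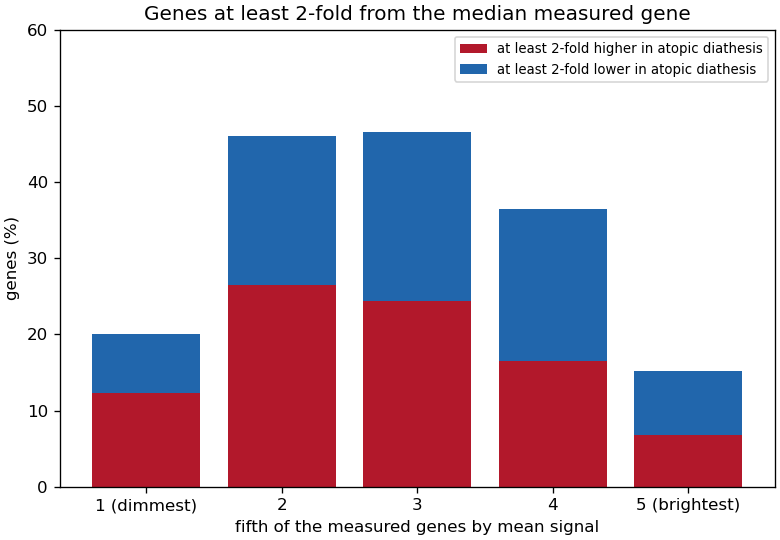
Percent of genes at least 2-fold higher (red) or lower (blue) in atopic diathesis microglia than the median measured gene (vertical axis), stacked, in each quintile of the measured genes by mean signal (horizontal axis, dimmest at left). The totals are 20.1, 46.1, 46.6, 36.5 and 15.2%, and in the dimmest quintile the background filter itself bounds the differences.

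Many genes were well above background on 1 array only. Stx16, a syntaxin of endosome to Golgi transport, was detected only in atopic diathesis microglia, at least 211-fold higher, and Rtp4, an interferon-induced gene, at least 72.4-fold. Celsr2, an adhesion cadherin, was detected only in control microglia, at least 212-fold lower in atopic diathesis, and the DNA helicase gene Mcm9 at least 169-fold lower. The next highest bounds belonged to the kinase gene Lrrk1 (at least 92.2-fold), the receptor kinase Grk3 (86.1) and Epc1 (77.8) on the atopic diathesis side, and to Tstd3 (111), Fam78a (94.4) and the splicing factor Srrm4 (92.2) on the control side. Celsr2, Mcm9, Fam78a, Lrrk1 and Epc1 have more than 1 probe on the array, and each bound rests on the brightest probe alone. Altogether 2821 genes were above background on the atopic diathesis array only and 1448 on the control array only. Bounds of at least 2-fold were reached by 1671 and 740 of them relative to the median gene, and by 1225 and 1080 on the 75th percentile scale. With normexp these latter counts were 626 and 372. All such bounds depend on how background is treated: under normexp or uncorrected signals, 161 of 162 values for the 81 genes followed, Ednrb aside, were smaller, at a median of 0.515 times the bound printed here.

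Genes that mark homeostatic microglia were on both arrays at similar signals. All 22 were measured, and 20 lay within 2-fold of the median gene. The purinergic receptor gene P2ry12 had a log2 difference of -0.05, the fractalkine receptor Cx3cr1 of 0.15, Sall1 of -0.10 and Tmem119 of -0.44. The exceptions were the transcription factor Mef2c, at 3.50, and the adhesion receptor Adgrg1, at -1.05. P2ry13 (-0.72) and Rtn4rl1 (-0.76) stayed within 2-fold. The list's median of -0.09 stood at percentile 28.2 of random lists with matched signal.

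Disease-associated microglia genes lay below the median gene in 12 of 17 measured cases. None was at least 2-fold higher and 3 were lower: the lipoprotein lipase gene Lpl (-2.24), the beta-glucan receptor Clec7a (-2.05) and Apoe (-1.06). Ccl6 read -0.89, Trem2 -0.04, Tyrobp -0.13 and Axl -0.57. Of genes above background on 1 array only, Igf1 was at least 10.5-fold lower, while Fabp5 and Lilrb4a went the other way, at least 2.93- and 2.31-fold higher. The percentile was 7.64. Among genes tied to microglial reactivity in nerve injury and pain, 14 of 16 measured lay within 2-fold (percentile 40.6). The Toll-like receptor genes Tlr4 (2.49) and Tlr2 (1.26) were higher, whereas the purinergic receptor P2rx4 (0.05), P2rx7 (-0.41), Csf1r (-0.32), Cd68 (-0.48) and the transcription factor Irf8 (0.22) were within 2-fold. Cybb, the catalytic subunit of the phagocyte oxidase, was detected on the control array only, at least 14.4-fold lower.

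Inflammatory cytokine genes showed no shared direction. Il1b, encoding interleukin-1 beta, had signals of 26.4 and 249 and a log2 difference of 3.27, while Il1a was at -1.46. The other 8 of 10 measured genes lay within 2-fold, among them Tnf (0.54), Ccl2 (0.05), Ccl3 (0.25), Ccl4 (-0.14) and Ccl12 (-0.49). Cxcl2 was above background on the control array only, at least 25.8-fold lower, and the cyclooxygenase gene Ptgs2 on the atopic diathesis array only, at least 4.26-fold higher. Of 9 NF-kappaB feedback genes, Birc3 was higher (2.35) and Tnfaip3 lower (-1.08), with Nfkb1 at -0.79 and Icam1 at -0.80. Of 12 Toll-like receptor and adaptor genes, 4 were higher: Tlr4, Tlr2, the kinase Irak4 (1.98) and the Tlr4 partner Ly96 (1.70). Traf6 was lower (-1.99) and Tlr9 read -0.90. Of 6 measured interferon-stimulated genes, the RNA sensor Ddx58 was higher (1.08) and Ifit3 lower (-1.39), with Ifih1 at 0.73 and Bst2 at -0.36. A further 5 were above background in atopic diathesis microglia only, 2 of them, Rtp4 included, by at least 2-fold. In control microglia only there was 1, also by at least 2-fold, and 13 were not well above background on either array. The percentiles of these 4 lists were 75.5, 35.7, 78.0 and 85.0.

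Genes of allergic responses were partly below detection. For type 2 cytokines and their receptors, 7 of 20 genes were measured, 6 of which lay below the median gene (percentile 14.6). Csf2rb, the common beta receptor chain, was lower (-1.40), and the receptor chains Il4ra (-0.69), Il13ra1 (-0.77) and Il5ra (-0.48) were within 2-fold. Crlf2, the receptor of thymic stromal lymphopoietin, was above background in atopic diathesis microglia only, at least 13.2-fold higher, and Il2rg, the common gamma chain, in control microglia only, at least 6.59-fold lower. Il4, Il5, Il13 and Tslp were not well above background on either array. Of 7 genes of type 2 macrophage activation, Ccl24 (2.29) and the lectin Mgl2 (1.68) were higher, with Il4ra and Myc (-0.74) within 2-fold (percentile 61.2). Arg1 and Mrc1 were not well above background on either array. Among 13 measured Fc receptor and signalling genes, 4 were higher: the tyrosine kinases Btk (3.84) and Lyn (1.65), and the receptors Fcgr4 (1.25) and Fcgrt (1.05). The high-affinity IgG receptor Fcgr1 was lower (-1.01), and Plcg2 (-0.74) and Fcer2a (-0.79) were within 2-fold (percentile 41.8). The alpha chain of the IgE receptor, Fcer1a, was not well above background on either array. Of 8 histamine, leukotriene and prostaglandin genes, the cyclooxygenase Ptgs1 was higher (1.75), the histamine-degrading enzyme Hnmt lower (-1.63), and Alox5ap (-0.35) and Hpgds (-0.46) within 2-fold (percentile 66.3). Alox5, the 5-lipoxygenase, was detected in atopic diathesis microglia only, at least 7.41-fold higher.

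The endothelin receptor gene Ednrb was detected in atopic diathesis microglia only. Its probe on chromosome 14 at 104214484 to 104214543 (mm9, minus strand) had a signal of 4.94 in control and 420 in atopic diathesis microglia, at least 21.7-fold higher and at least 15.4-fold on the 75th percentile scale. A second Ednrb probe, at 104220870 to 104220929 on the same strand, was not well above background on either array, with signals of 5.85 and 4.75. Bounds as high were reached by 116 of the 2821 genes detected on the atopic diathesis array only and by 62 of the 1448 on the control array only. With normexp the Ednrb bound was 5.21-fold, and with uncorrected signals 4.27-fold. The other 7 endothelin genes (Edn1, Edn2, Edn3, Ednra, Ece1, Ece2 and Ecel1) were not well above background on either array.

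Antigen presentation genes differed member by member. In the MHC class II and co-stimulation list, the co-stimulatory ligand Cd86 was lower (-3.38), as was the inhibitory ligand Cd274 (-2.35), and H2-Ob was higher (2.42), with Cd80 at -0.50 and the invariant chain Cd74 at 0.66 (9 measured, percentile 17.6, but 80.3 with the brighter probes only). The immunoproteasome genes Psmb8 (2.10) and Psmb10 (1.42) were higher among 10 class I genes, while H2-K1 (-0.87) and H2-T23 (-0.93) were within 2-fold (percentile 53.3). Of 10 complement genes 5 lay above the median gene and 5 below, 1 being at least 2-fold higher and 1, the receptor C5ar1, lower (-2.89), with C1qb (-0.33) and Itgb2 (-0.70) within 2-fold (percentile 43.0). The complement percentile was 5.76 with the brighter probes only and 65.3 without probes that share sequence with many genes. The kinase receptor Mertk (-1.49) and Stab1 (-1.22) were lower among 9 phagocytic and scavenger receptor genes, of which 8 lay below the median gene, with Axl and Havcr2 (-0.42) within 2-fold (percentile 8.74). In the lysosome list, 19 of 22 genes were within 2-fold (percentile 27.7). The higher ones were Man2b1 (1.37) and Ctsc (1.18), 1 gene was lower, and Psap (-0.69), Npc2 (-0.70) and Ctsa (-0.98) were within 2-fold. The TGF-beta list held the highest value of any measured list member: Nrros, a TGF-beta activating partner in microglia, read 218 and 4712 (log2 difference 4.47), and Smad4 (-2.21), Smad2 (-1.66) and Smad7 (-1.18) were lower (9 measured, percentile 35). Tgif1, at 2.49, rested on a probe that shares sequence with probes of many other genes.

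Genes of energy metabolism lay on both sides. Among 19 measured oxidative phosphorylation genes, 7 were lower and 3 higher (percentile 14.7). Atp5a1 (-2.69), Cox4i1 (-2.39), Cox5a (-2.13) and Ndufs3 (-2.10) had the lowest values, and Ndufs1 (2.57), Cox6c (2.53) and Cox5b (1.45) were the higher ones. A further 3, Uqcrc1, Uqcrfs1 and Ndufv1, were above background in atopic diathesis microglia only, at least 4.32-, 2.26- and 2.03-fold higher. In glycolysis 4 of 17 genes were lower, namely Pgk1 (-2.05), Tpi1 (-1.41), Aldoa (-1.19) and Hk1 (-1.01), and none was higher (percentile 16.4). With the brightest probe per gene the glycolysis percentile was 50.3. Hk1 read 0.029 when only the brighter probes entered. Of 8 cholesterol genes 3 were higher, Hmgcs1 (1.64), the efflux transporter Abca1 (1.14) and Fdft1 (1.01), and 3 lower, Soat1 (-2.61), Srebf2 (-1.53) and Apoe, with Abcg1 at -0.81 (percentile 18.5, but 85.5 with no background filter). Of members above background on 1 array only, 3 were at least 2-fold lower and 1 at least 2-fold higher. Cytosolic ribosomal protein genes were within 2-fold in 23 of 25 cases (percentile 84.1). Rpl18 (1.49) was higher and Rplp0 (-1.80) lower, and Rpl7 (-0.51) and Rps9 (-0.33) came next.

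Stress genes were split as well. Of 12 oxidative stress genes 5 were higher and 2 lower. Txnrd1 (2.04), Hmox1 (1.69) and the phagocyte oxidase subunit genes Ncf4 (2.46) and Cyba (1.13) were among the higher ones, and Gclc (-1.15) and Prdx6 (-1.02) were lower (percentile 90.2). With probes that share sequence with many genes left out, which drops Cat, the list stood at 97.8, past the limit for standing apart, but with no background filter it stood at 40.2. Of 13 heat shock and unfolded protein response genes 3 were higher, Hspb1 (3.77), Herpud1 (1.74) and Sdf2l1 (1.54), and 3 lower, Hspa1a (-2.35), Dnajb1 (-1.89) and Xbp1 (-1.27), at percentile 32.3. Cell cycle genes were mostly undetected, 16 of 24 being not well above background on either array. The proliferation marker Mki67 had a log2 difference of 1.64 from signals of 24.5 and 74.8, and Pcna and Mcm6 were both at -0.03.

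Immediate early genes were the 1 list of 29 that stood apart from random lists, at percentile 0.075, where 1.45 lists would be expected by chance. Their median was -0.42, and 12 of 17 measured genes lay below the median gene. The AP-1 gene Junb was lower (-2.02), and the others were within 2-fold: Ier3 (-0.94), Ier2 (-0.93), Egr1 (-0.73), Klf4 (-0.65), Klf2 (-0.63), Fosb (-0.58) and Fos (-0.51) below, and Btg2 (0.37), Zfp36 (0.21) and Klf6 (0.17) above the median gene. The 3 members outside this median were above background in atopic diathesis microglia only. Of these Fosl2 went clearly the other way, at least 34.3-fold higher. The bounds of Egr3 (at least 1.41-fold) and Nr4a1 (at least 1.25-fold) fell short of 2-fold. The median was -0.25 with quantile normalization and with the authors' values. The percentile was 2.57 with probes above background on at least 1 array and 7.20 with no background filter.

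**Figure D3:**
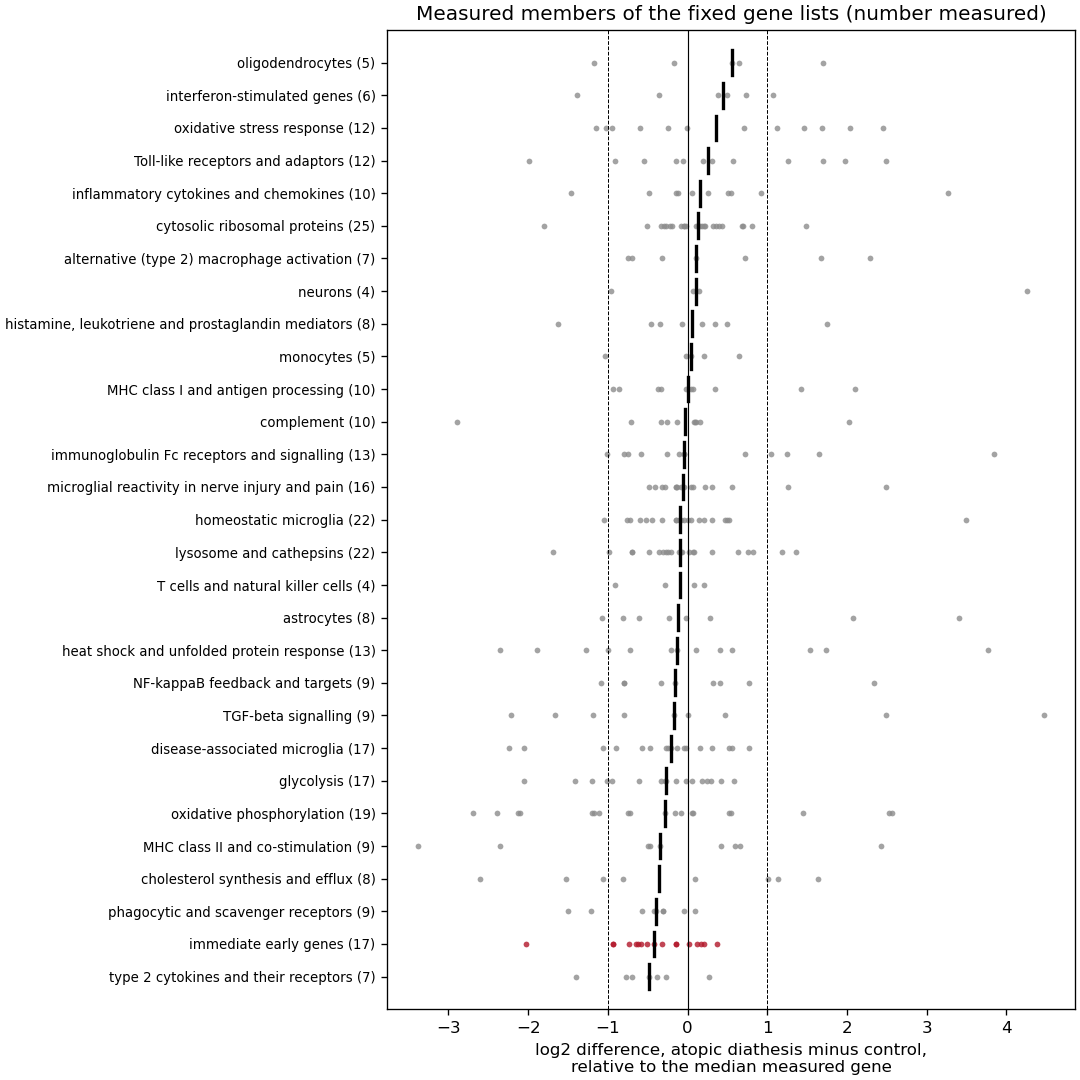
Log2 difference of each measured member (points), atopic diathesis minus control and relative to the median measured gene, for the 29 fixed lists with at least 4 measured genes, with the number measured in parentheses; black bars are list medians and dashed lines mark 2-fold. Immediate early genes (red), with a median of -0.42, are the 1 list outside the central 95% of random lists.

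Markers of most other cells were few on both arrays. The largest shares measured were those of astrocytes (8 of 16), monocytes (5 of 12) and oligodendrocytes (5 of 16). Of 16 astrocyte genes 8 were measured: Atp1b2 (3.41) and S100b (2.08) were higher and Ntsr2 lower (-1.08), while Gfap (-0.23), Slc1a3 (-0.01), Aldoc (-0.61) and Mlc1 (-0.81) were within 2-fold (percentile 41.6). Acsbg1, Sox9 and Gja1 were above background in atopic diathesis microglia only, by at least 33.9-, 13.1- and 12.5-fold, and Aqp4, Aldh1l1, Slc1a2, Gjb6 and Slc4a4 were above background on neither array. Of 5 measured oligodendrocyte genes, Cnp was higher (1.70), Ermn lower (-1.18), and Mbp (0.56) and Trf (0.64) within 2-fold (percentile 88.5). Cldn11, Mag and Ugt8a were above background in atopic diathesis microglia only, by at least 15.6-, 2.53- and 2.43-fold. None of 11 oligodendrocyte precursor genes was well above background on either array. Of 4 measured neuronal genes Eno2 was higher (4.26), with Chat at 0.14 and Map2 at -0.95 (percentile 57.7). The Snap25 value of 0.07 came from a probe that shares sequence with many genes, as did that of the monocyte marker Ms4a4c (0.05).

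Blood cell markers were largely undetected. Among monocyte genes 5 of 12 were measured, Ly6c1 being lower (-1.03; 0.42 once probes above background on a single array entered) and Lyz2 (0.21) and F10 (-0.01) within 2-fold, and Ccr2 was above background on neither array (percentile 57.9). Csf3r (0.01) was the single neutrophil marker measured, and S100a8 and S100a9 were above background on neither array. Of 4 T and natural killer cell genes all were within 2-fold, Nkg7 at -0.91, Cd4 at -0.28, Prf1 at 0.20 and Il7r at 0.09 (percentile 41.2). The B cell genes Cr2 (0.29) and Pax5 (0.24), and the erythroid Tfrc (-0.34), were within 2-fold. Siglecf was higher (1.33) and Il5ra at -0.48 among mast cell, basophil and eosinophil genes, 14 of which were above background on neither array. In the dendritic cell list Tcf4 was higher (1.56), with Siglech at -0.09 and Bst2 at -0.36. Stab1, lower at -1.22, was the only border-associated macrophage marker measured, with 11 above background on neither array. Endothelial genes Vwf (0.50), Kdr (-0.27) and Abcb1a (-0.53), mural and fibroblast genes Tagln (0.30) and Igfbp2 (-0.38), and the Schwann list gene Egr2 (-0.32) were within 2-fold, and Pmp22 was lower (-1.05). Of the sex-linked genes, the Y-linked Ddx3y had signals of 221 and 231 and Eif2s3y of 38.4 and 99.5 (log2 differences of 0.10 and 1.41), and the X-linked Xist was not well above background on either array.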

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

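The references to the median gene, the brightest quintile and the left-out probes, and the scalings of the Ednrb bound, were chosen after the data were seen. With 1 array per group leaving out an array was not possible, and signal over background limits what can be compared, since most probes were dim. No paired analysis was possible because each group has 1 array and no test was made.

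Counts of genes at least 2-fold higher and lower, 988 and 2506 on the main scale, moved with the filter, the scaling, the background treatment and the threshold: to 1712 and 1307 with detected-probe scaling, 3367 and 3846 with probes above background on at least 1 array, 3659 and 5065 without a filter, 398 and 1309 with the brighter probes only, 1596 and 1436 relative to the median gene, and 126 and 155 in the brightest quintile by that same reference. The lower count was 1177 with normexp, 1120 with uncorrected signals and 4165 at 1.5-fold; at 4-fold the counts were 361 and 843. Filters and thresholds alter the number of genes by construction. Detected-probe scaling and the median gene as reference shift all genes by the same amount, which alone gives their counts. The cause of the moves with background treatment was not tested. Genes above background on 1 array with a bound of 2-fold, 1225 for atopic diathesis and 1080 for control, numbered 654 and 533 at 4-fold and 626 and 372 with normexp. The Ednrb bound, 21.7-fold, was 5.21-fold with normexp and 4.27-fold with uncorrected signals, which keep background in the dim value, and 20.2- to 21.7-fold under the other scalings.

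The counts in this paragraph leave out the median and detected-probe scalings, which shift all genes alike and cannot move a value relative to the median gene, and lists that keep all measured members in the test of members that no other list names. Of 360 list percentiles under the other alternatives, 354 stayed on their side of the limits. That leaves direction open: 33 of them, in 18 of 29 lists, lay on the other side of percentile 50 from the main value. Immediate early genes went to 2.57 (at least 1 array) and 7.20 (no filter), cholesterol genes from 18.5 to 0.35 (at least 1 array) and 1.5 (brighter probes) but also to 85.5 (no filter) and 63.9 (members that no other list names), phagocytic receptors from 8.74 to 1.94 (no filter), and oxidative stress genes from 90.2 to 97.8 without shared-sequence probes and to 40.2 with no filter. MHC class II genes went from 17.6 to 80.3 (brighter probes) and 51.7 (no filter); the cause of these moves was not tested. Among 371 named genes, 3312 of 3968 values under alternatives moved by at most 1 SD of spot error, 651 moved further and 5 turned sign: Cyria (0.57 and 0.67) and Ly6c1 (0.42 and 0.52) with probes above background on at least 1 array and with no filter, and Hk1 (0.029) with the brighter probes. Of 405 bounds for 81 other genes, 141 moved by at most that SD and 264 further, 153 of these among the 162 with normexp or uncorrected signals, where 161 were smaller than the main bound (median ratio 0.515).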

Other observations

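All genes in the next 2 paragraphs were picked after their values were seen; of the tests after those, the correlation of probes of one gene, the loess correction and the nearest-gene matching were fixed before their results were seen, and the others afterwards.

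Among the brightest quintile of genes, where the smallest share lay past 2-fold, some single genes outside the fixed lists still lay far apart. Fnip2, a folliculin-interacting protein, was 26.2-fold higher in atopic diathesis microglia, Wtap, a subunit of the RNA adenosine methyltransferase complex, 11.9-fold, Taf12 9.5-fold, Uhmk1 9.44-fold and Zbed4 9.09-fold. Idh2, the mitochondrial isocitrate dehydrogenase, was 19.7-fold lower, with signals of 4593 and 228, Tmem63a 12.4-fold, Gpr107 11.7-fold, Urm1 10.3-fold and Ubac2 9.96-fold lower. Each rested on 1 measured probe.

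Genes read by a pair of probes agreed more often than chance pairing gives. Of 977 genes with exactly 2 measured probes that share no stretch of 16 bases with each other, 165 had both probes at least 2-fold from the median gene on one side (79 higher, 86 lower), against a mean of 71.4 and a range of 47 to 95 when probes were paired at random 1000 times. A further 106 genes had pairs that share sequence and are left out of these counts. In 37 genes the probes lay at least 2-fold apart from the median gene in opposite directions. Since the share past 2-fold varied with signal, like signal of the probes of one gene may add to the gap between 165 and 71.4. Among genes not named in the report's extremes, which hold the 2-probe gene Zpr1, Rbis (18.7-fold), Kansl2 (17.0-fold), Fbxw11 (11.6-fold), G6pc3 (8.87-fold) and Stoml2 (7.92-fold) led those that were higher, and Clip1 (18.0-fold), Tsr1 (16.7-fold), Msto1 (14-fold), the proteasome subunit Psmc2 (12.5-fold) and prohibitin 2, Phb2 (8.81-fold), those that were lower; the probes of Zpr1, Rbis, Tsr1, Msto1 and Psmc2 share sequence with each other and are no separate readings.

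Most of the brightest probes share sequence with probes of many other genes, and their signal need not come from the gene they are named for. Of the 100 brightest measured probes, 80 share at least 16 bases with probes of 10 or more gene names, against 4.0% of the 11263 measured probes. Snap25, a neuronal gene, read 82155 and 84015 from such a probe, Itgam 92920 and 82663, Ms4a4c 96707 and 97602 and Cat 38379 and 37444, and Ciita and Tgif1 were also read by such probes alone. Of these 451 probes 7.54% were at least 2-fold from the median gene, against 35% of the other measured probes and 22.2% of the others when weighted to the same 20 bins of mean signal; within a bin the signals still differ.

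The 1495 probes of olfactory and vomeronasal receptor genes were dim on both arrays, with 1.54% well above background on each, and their 75th percentile of signal was 5.41 in control and 7.59 in atopic diathesis microglia, a log2 shift of 0.49 beside 0.47 for all probes.

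About 32.9% of measured genes lay at least 2-fold from the median gene, in both directions. Probe-specific error is not the whole source in genes with a pair of probes: of 202 genes whose probes share no stretch of 16 bases and both lay past 2-fold, 165 (81.7%, 95% interval 75.6 to 86.8) had them on one side, where such error would put about as many on opposite sides. A part from it stays open, since differences of probes of one gene correlated with r = 0.45 across genes, and 0.37 where they share no sequence, between the limits of 0.2 and 0.5 set for it. Of pairs of spots of one probe 0.217% differed by 2-fold or more, but this leaves out the error of separate sorts, amplifications and hybridizations and decides nothing about these. Sampling of few RNA molecules before amplification stays open too: the share past 2-fold was 3.06 times as high in the middle quintile of signal (46.6%) as in the brightest quintile (15.2%), but any error that grows at lower signal gives such a ratio. Probes that share sequence with many genes lowered the share at high signal. In the brightest quintile of measured probes, 0.775% of 258 such probes were past 2-fold, against 17.1% of the other 1995. A difference between the mice cannot be told apart from these sources of error, with 1 array per group.

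Immediate early genes stood below random lists in atopic diathesis microglia. Random lists were matched on mean signal, so a bias that depends on signal alone would move list and random genes nearly alike. The percentile of 0.075 for the 17 measured genes therefore argues against such a bias as the source of their standing below random lists. It was 0.08 after loess correction and 0.07 after quantile normalization, but these corrections could hardly move it. The list median was -0.40 after loess, against -0.42, so a smooth trend with mean signal accounts for little of it. Quantile normalization and the authors' values brought the median to -0.25, so part of its size relative to the median gene may still come from such a bias. Coarse matching of bright genes is not the whole cause, since the percentile was 0.02 with the 50 nearest genes. Leaving out any 1 gene gave percentiles of 0 to 0.3. Cell isolation induces such genes, so a longer or warmer isolation of the control cells may be the source. The list of heat shock and unfolded protein response genes, at percentile 32.3, neither stood apart nor lay at or above 50. That list mixes both kinds of genes. Of its 13 measured members 3 were lower, Hspa1a and Dnajb1 among them, and 3 were higher, Hspb1 among them. The list therefore leaves this source open. A difference between the mice also stays open with 1 array per group, and 1.45 of 29 lists were expected to stand apart by chance.

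Ednrb, which astrocytes are known to express, was detected in atopic diathesis microglia only. That reading rests on 1 probe, as a second Ednrb probe, at 5.85 and 4.75, was not well above background on either array. Whether the signal is specific to the first probe was not tested. RNA of astrocytes in the atopic diathesis sample is a candidate explanation that the markers do not settle. Of 16 markers 5 were higher or detected there alone (S100b, Atp1b2, Gja1, Sox9 and Acsbg1). Gfap (-0.23), Slc1a3 (-0.01) and Aldoc (-0.61) were within 2-fold, and Aqp4 and Slc1a2 were above background on neither array. Sorting would be expected to remove such cells, but 8 of the 16 markers were well above background on both arrays. Sampling of few RNA molecules also stays open: bounds as high were about as common among genes detected in control microglia only (4.28%) as in atopic diathesis microglia only (4.11%), a ratio of 1.04 that any source acting in both directions would give. A difference between the mice cannot be told apart from these with 1 array per group.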
